A study of Arabidopsis thaliana with 26 samples.

How the data were processed

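Gene expression was measured on 26 microarrays of RNA from Arabidopsis seedling roots, in 10 groups taken from the sample titles and source names. The time series used cells sorted for green fluorescent protein (GFP) under the promoter of SCARECROW (SCR), a transcription factor gene of the endodermis and quiescent centre. Per the labels' protocols, seedlings went onto medium with 1 µM 2,4-D, a synthetic auxin, at 2 days after germination, and root tips of 250 µm were protoplasted and sorted after 0 h (3 arrays) and after 24 h, 48 h, 72 h and 96 h (2 arrays each). Quiescent centre (QC) cells were sorted with the WOX5 promoter at 3 days after germination, per the labels. They came from a separate wild type harvest, from wild type plants grown with the jkd mutant and from jkd plants (3 arrays each). Whole meristems of wild type and jkd plants gave 3 arrays each. The jkd mutant lacks function of JACKDAW (JKD), a zinc finger transcription factor of the ground tissue. The titles of the QC arrays name the allele jkd-4 and the wild type line Col-0, while the meristem labels name only jkd and wild type. The descriptions of the jkd QC arrays and of the jkd meristem arrays cite another profile and a control role, so the genotype was read from the titles and source names. The labels do not say whether the arrays of a group came from separate batches of plants, so every p-value measures only the spread between these arrays, which may be technical.

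Sorted protoplasts went straight into extraction buffer, and RNA was purified on microcolumns with DNase treatment, amplified with the Ovation Pico system and labelled with biotin, per the labels' protocols. The authors deposited the values as MAS5 signal intensities on a linear scale, 1 per probe set and array, per the submitters' processing notes. The MAS5 version, its scaling target, its detection calls, the array type and the genome build are not given in the sources used here. The smallest signal was 0.02 and the largest 42893.39. The mean signal after trimming 2% of the values at each end lay between 251.1 and 257 on every array. Values carry 1 decimal in the 14 arrays of the time series and of the separate QC harvest and 2 decimals in the other 12 arrays. The deposited matrix and the series value table hold the same numbers: 23 columns were equal under their names, and 3 columns without a replicate number were equal as a set.

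Each table holds 16384 probe sets of 16255 loci, each probe set with 1 locus code in the deposited matrix. The probe set numbers run from 244901 to 261683, and only 401 of them belong to chromosome 2, so most chromosome 2 genes were not analysed here. Neither were WOX5 and PLT2. Gene symbols were taken from the RefSeq gene table of assembly TAIR10.1, which holds 16032 of the loci, and a locus code stands where it gives no symbol. Probe sets of plastid genes numbered 80 and those of mitochondrial genes 61. A further 670 probe sets have a name ending that marks possible cross-hybridisation.

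All tests used log2(signal + 16), which understates the change of weak genes, with no further normalization. In each fit, probe sets with a mean at or above the 30th percentile were tested, 11469 in every case. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), and p-values were adjusted by the Benjamini-Hochberg method. A gene passed at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 11 arrays sorted with the SCR promoter shared a fit for all comparisons between times, and were joined by the separate QC harvest for comparisons with the QC. The QC against the meristem, jkd against wild type in each tissue and the QC harvests against each other were each fitted on their 6 arrays, and the difference of the jkd effect between tissues on 12 arrays. Errors written with ± are standard errors from these fits. The comparison of 96 h with 24 h and the tests without the 0 h arrays were added after the data had been seen.

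Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, for lists with at least 5 tested members. The 19 lists were quiescent centre and stem cell niche, the SHORT-ROOT and SCARECROW network, endodermis Casparian strip, endodermis suberin, auxin response, lateral root initiation, auxin synthesis and transport, DNA replication and S phase, G2 and mitosis, cell cycle inhibitors, cytokinin response, gibberellin metabolism, root cap, xylem, phloem, epidermis patterning, root hair and cortex markers, and stress and protoplasting. They name 218 members, of which 140 are on the tables. The cortex list has 0 members there and gives no result. QC-enriched and QC-depleted genes were those that passed and differed by at least 1 on the log2 scale between the separate QC harvest and the wild type meristem. No list call was kept with an estimated correlation, while the shift of the QC-enriched genes was. The genes named are JKD, SCR, SHR and PLT1 in every comparison, up to 4 passed members per list by smallest adjusted p, and the largest changes among passed genes whose arrays do not overlap between the groups. These are up to 8 in each direction for the main comparisons and 3 for the others. The groups, tests, lists, the rule for named genes and the alternatives, except those said to be added, were chosen before the data were examined.

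The tests were checked on simulated data for the 11469 tested genes of each comparison. Of genes given a change of 1 on the log2 scale, the fit recovered 3.1% at 24 h against 0 h, 1.0% at 96 h against 24 h, 9.4% at 24 h against the QC, 54.2% between the QC and the meristem, 3.3% for jkd in the QC and 53.7% for jkd in the meristem. At a change of 2 these shares were 51%, 43.8%, 65.6%, 95.6%, 29.2% and 95.5% in the same order. Each simulation gave a change of each size to only 89 to 98 of the 11469 genes. Far more genes passed in some real comparisons: 5522 at 24 h against 0 h, 3630 at 24 h against the QC and 6690 between the QC and the meristem. The Benjamini-Hochberg cutoff is looser where more genes change. For such comparisons the shares therefore do not measure the sensitivity of the real test. In each of these simulations camera found 10 of 10 moved lists and called 0 of 10 unmoved lists. The simulated genes varied independently of each other. This check therefore cannot tell how camera behaves where the genes of a list are correlated. The number of arrays limits the precision of every value. Alternatives covered the pseudocount (1 and 64), the filter on weak genes, quantile normalization, the eBayes settings, array weights, a joint fit of all 26 arrays, a block for the replicate number, the other QC harvest as the QC, leaving out organellar probe sets and leaving out each array in turn.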

Results

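The series holds 2 experiments on the Arabidopsis root. In the first, cells marked by the SCR promoter were profiled over 96 h of treatment with the synthetic auxin 2,4-D. SCR is a gene of the endodermis and of the quiescent centre, so the sorted cells may hold both. The title names a change from endodermis to quiescent centre, the small group of slowly dividing cells that maintains the root stem cells. In the second, sorted QC cells and whole meristems of the jkd mutant were set beside wild type. Median signals ranged from 57.45 to 74.15 in the 8 treated arrays, from 83.2 to 102.6 in the 3 arrays at 0 h, from 65.52 to 86.7 in the QC arrays and from 75.24 to 85.7 in the meristem arrays. Correlations between replicates were 0.981 to 0.992 in the wild type meristem and 0.962 to 0.969 in the separate QC harvest. They were 0.955 to 0.974 within the treated times, but only 0.889 to 0.962 at 0 h and 0.908 to 0.946 in the QC arrays grown with jkd.

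Transcripts of the plastid and mitochondrial genomes differed between arrays of the same group. At 0 h, replicate 5 had a mean plastid log2 signal of 10.01, against a mean of 7.37 in replicates 1 and 3. The 8 treated arrays lay between 8.99 and 10.02 for plastid genes and between 7.23 and 8.45 for mitochondrial genes. Both meristem groups were low and narrow, with plastid means of 7.25 ± 0.08 in wild type and 7.24 ± 0.12 in jkd (SD, n = 3 each). The separate QC harvest stood at 9.36 ± 0.13 and the QC arrays grown with jkd at 9.89 ± 0.36 (SD, n = 3 each).

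**Figure D1:**
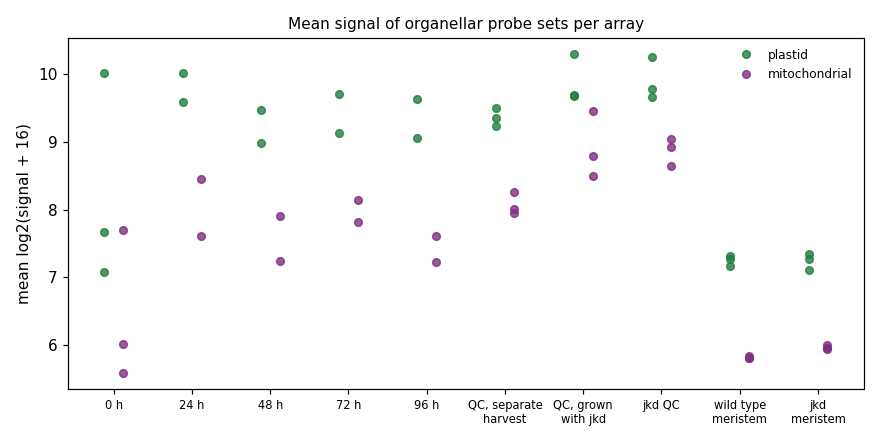
Mean log2(signal + 16) of the 80 plastid (green) and 61 mitochondrial (purple) probe sets, 1 point per array, in each of the 10 groups. At 0 h replicate 5 stands at 10.01 for plastid genes, within the range of the treated arrays, while the mean of replicates 1 and 3 is 7.37.

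No untreated cells were profiled at 24 to 96 h. In every change against 0 h, 2,4-D therefore cannot be told apart from the greater age of the seedlings. After 24 h of 2,4-D, 4 of 6 tested genes of the Casparian strip, the lignin barrier of the endodermis, and 7 of 9 genes of G2 and mitosis had fallen. Signal had risen for AIL6 and BBM, transcription factors of the PLETHORA group that pattern the root stem cell niche. CASP2, a scaffold protein of the strip, fell by 4.58 ± 0.33 on the log2 scale (n = 2 against 3, adjusted p = 7.77e-07), from a mean signal of 5049 to 196.6. PER64, the peroxidase of the strip, fell by 4.84 ± 0.56 (adjusted p = 4.54e-05). AIL6 rose by 2.55 ± 0.34 (adjusted p = 5.94e-05) and BBM by 2.51 ± 0.39 (adjusted p = 0.000188). The signal of BBM at 0 h is near background (a mean of 22.03), so the size of its rise at this and later times depends on the pseudocount. In all, 5522 of 11469 genes passed, 2372 higher and 3150 lower than at 0 h.

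By gene list at 24 h, 4 of the 6 tested Casparian strip genes fell, also 4 when adjusted over the list alone, and CASP4 fell by 5.96 ± 0.47 to a mean of 12.2, near background, where the size of the change depends on the pseudocount. The list's median log2 change was -4.02 (camera adjusted p = 0.0143, and adjusted p = 0.58 with an estimated correlation). Of the 9 genes of G2 and mitosis, 7 fell, 8 when adjusted over the list alone, with a median of -1.38 (camera adjusted p = 0.0143, and adjusted p = 0.58 with an estimated correlation). Among them the mitotic kinase AUR1 fell by 2.27 ± 0.39 and the cyclin CYCB1;1 by 2.21 ± 0.39. Genes of DNA replication and S phase fell in 2 of 5 cases, also 2 when adjusted over the list alone. These were TSO2, a ribonucleotide reductase subunit, by 3.61 ± 0.37, and PCNA1 by 1.66 ± 0.37. Cell cycle inhibitors fell in 4 of 7 cases and rose in 1, against 5 and 1 when adjusted over the list alone. SIM, which holds back mitosis in endoreduplicating cells, fell by 2.22 ± 0.37. Of the suberin genes, 2 of 5 fell, ASFT by 3.28 ± 0.62, and KCS20 rose by 1.63 ± 0.57, with the same counts when adjusted over the list alone.

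Genes of the QC and stem cell niche were mixed at 24 h: 2 of 8 rose and 1 fell, with the same counts when adjusted over the list alone. TAA1, an enzyme gene of auxin synthesis, fell by 2.37 ± 0.34. In the SHORT-ROOT and SCARECROW network, 2 of 8 rose and 1 fell, as they did when adjusted over the list alone. SHR itself rose by 1.24 ± 0.46 (adjusted p = 0.0399) and the zinc finger gene NUC by 1.20 ± 0.45, while SNE fell by 1.71 ± 0.34. For SCR the difference was 0.32 ± 0.39 (adjusted p = 0.515), for JKD 0.81 ± 0.50 (adjusted p = 0.199) and for PLT1 -0.29 ± 0.46 (adjusted p = 0.621). Auxin response genes fell in 3 of 11 cases and rose in 1, also when adjusted over the list alone. IAA14 fell by 2.34 ± 0.42 and IAA19 by 1.46 ± 0.35, while IAA13 rose by 1.82 ± 0.34. In auxin synthesis and transport, 3 of 6 fell and 1 rose, as they did when adjusted over the list alone. The influx carrier LAX3 fell by 2.43 ± 0.38 and the enzyme gene YUC8 rose by 1.13 ± 0.37. Of the lateral root initiation genes, 1 of 4 rose, ARF7 by 1.41 ± 0.31, and 1 fell, GATA23 by 2.72 ± 0.86. That list had a median of 0.20 and a mean of -0.23, so the 2 differ in sign.

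Among lists of hormones and other cell types at 24 h, all 4 tested gibberellin metabolism genes fell, and 0 of 4 cytokinin response genes passed with limma, also when adjusted over each list alone. Among the former, GA20OX2 fell by 1.88 ± 0.46. Root cap markers had 1 of 5 lower, COBL2 at -0.96 ± 0.35, and 0 when adjusted over the list alone. One marker each passed in the xylem list (1 of 2, TMO5 rose by 1.26 ± 0.48), the phloem list (1 of 1, OPS rose by 2.45 ± 0.34), the epidermis list (1 of 2, MYB23 fell by 1.37 ± 0.54) and the root hair list (1 of 2, COBL9 fell by 2.15 ± 0.45). Over the list alone 1 further xylem gene was lower. Of the stress and protoplasting genes 2 of 11 rose and 1 fell, with the same counts when adjusted over the list alone. DREB2A rose by 1.14 ± 0.27 and JAZ1 by 1.16 ± 0.30, while JAZ10 fell by 2.59 ± 0.46. This list's median was 0.23 and its mean -0.10, with camera pointing up at an adjusted p of 0.658. With these gene groups moved the organellar transcripts, with median log2 changes of 1.70 for plastid and 1.43 for mitochondrial genes. Large rises were those of the mitochondrial ATMG01200 (7.60 ± 0.66) and of HB53, a homeodomain gene (5.48 ± 0.33), and arabinogalactan protein genes fell far (AGP24 at -6.92 ± 0.36, AGP14 at -6.68 ± 0.39).

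The median log2 change of all genes at 24 h was -0.22, and quantile normalization moved it to 0.04. The share of calls that were higher then came to 53.19%, against 2372 of 5522 calls without it, while no named gene turned its direction.

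Against 0 h, 5 of 8 niche genes had risen and 5 of 6 Casparian strip genes had fallen by 96 h. BBM was up by 4.71 ± 0.39 (n = 2 against 3, adjusted p = 1.11e-06), and MYB56, which represses division in the QC, by 3.99 ± 0.44 (adjusted p = 1.2e-05). CASP2 stood at -6.17 ± 0.33 (adjusted p = 4.67e-08), and mean CASP4 signal went from 1882 to 2.3. In all 6013 genes passed, 2837 higher and 3176 lower, while with quantile normalization 53.74% of 5867 calls were higher. Of the QC and niche list, 5 of 8 rose and 0 fell, also when adjusted over the list alone, with ERF115 up by 2.77 ± 0.42 and PLT1 by 1.49 ± 0.46 (adjusted p = 0.014). The median of this list was 2.13 (camera adjusted p = 0.029, and adjusted p = 0.322 with an estimated correlation). In the Casparian list 5 of 6 fell, 6 when adjusted over the list alone, with a median of -5.92 (camera adjusted p = 7.69e-05, and adjusted p = 0.322 with an estimated correlation). CASP5 fell by 5.67 ± 0.40 and PER64 by 6.82 ± 0.56. Of the suberin genes 3 of 5 fell, ASFT by 4.17 ± 0.62, also 3 when adjusted over the list alone.

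In G2 and mitosis 2 of 9 fell at 96 h, CYCB1;3 by 1.77 ± 0.44 and AUR1 by 1.54 ± 0.39, and 1 rose, the kinesin gene HIK by 1.21 ± 0.41. In S phase TSO2 fell by 3.15 ± 0.37 and the helicase subunit gene MCM3 rose by 1.48 ± 0.34, 1 of 5 each. The median of that list was 0.63 and its mean -0.11, with camera pointing up at an adjusted p of 0.973. Inhibitors fell in 6 of 7 cases, SIM by 3.37 ± 0.37, and the remaining member, CCS52A2, rose by 1.96 ± 0.42. Auxin genes went both ways: in the response list 3 of 11 rose, IAA30 by 3.17 ± 0.39 and IAA13 by 2.71 ± 0.34, and 3 fell, with a median of -0.32 against a mean of 0.16 and camera pointing up. In auxin synthesis and transport YUC8 rose by 3.88 ± 0.37, while LAX3 fell by 3.78 ± 0.38 and YUC5 by 2.27 ± 0.40. SHR rose by 1.52 ± 0.46 and the brassinosteroid enzyme gene BR6OX2 fell by 2.11 ± 0.40, in a list with 2 of 8 higher and 2 lower, a median of 0.29, a mean of -0.07 and camera pointing down. Among stress genes 3 of 11 fell, JAZ10 at -3.38 ± 0.46 and RBOHD at -1.99 ± 0.44, with a median of 0.01, a mean of -0.67 and camera pointing down at an adjusted p of 0.973. For each list of this paragraph the counts were the same when adjusted over the list alone. Plastid genes stood higher by a median of 1.30 and mitochondrial genes by 0.94.

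At 48 h 5623 genes passed, with BBM up by 3.94 ± 0.39 and CASP2 at -5.33 ± 0.33. At 72 h 5659 passed, with BBM up by 4.43 ± 0.39, MYB56 by 2.71 ± 0.44 and PLT1 by 1.59 ± 0.46, and SCR reached 1.02 ± 0.39 (adjusted p = 0.0424). The joint test over the 4 times called 5926 genes, and 1026 genes had a linear trend between 24 h and 96 h in a fit without the 0 h arrays that was added after the data had been seen.

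**Figure D2:**
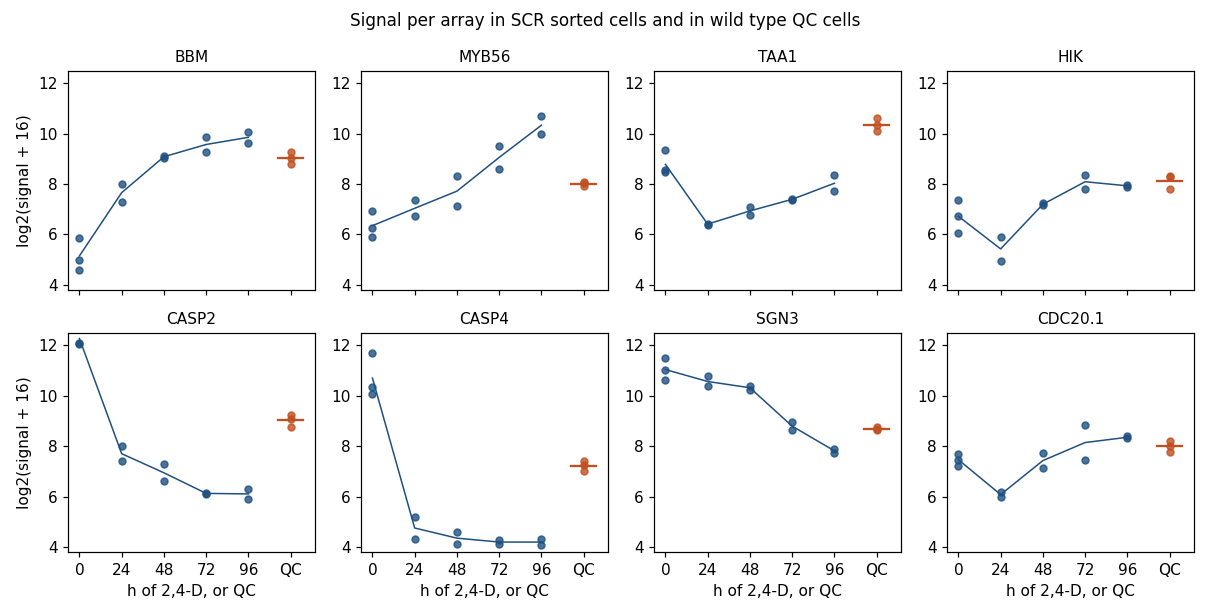
Log2(signal + 16) of 8 named genes, 1 point per array, over 0, 24, 48, 72 and 96 h of 2,4-D with a line through the group means, beside the 3 arrays of the separate QC harvest (orange, bar at their mean). BBM and MYB56 climb over the series, by 4.71 and 3.99 at 96 h against 0 h, CASP2 and CASP4 drop within 24 h, by -4.58 and -5.96, and TAA1, HIK and CDC20.1 dip at 24 h and stand higher again by 96 h. The name of the CDC20.1 probe set marks possible cross-hybridisation.

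Within the treated times the changes were smaller. Between 24 h and 96 h, compared after the data had been seen, BBM rose by 2.20 ± 0.43 (n = 2 each, adjusted p = 0.0116), YUC8 by 2.75 ± 0.40 and the auxin response gene IAA30 by 2.68 ± 0.42. SGN3, a receptor kinase that oversees the Casparian strip, fell by 2.75 ± 0.34 (adjusted p = 0.00131). Of the mitotic genes, HIK rose by 2.51 ± 0.44 and CDC20.1 by 2.28 ± 0.42. The name of the CDC20.1 probe set marks possible cross-hybridisation, and its close relative CDC20.2 has no probe set of its own, so the rise may not be of CDC20.1 alone. In all 443 genes passed, 226 higher and 217 lower. Of the niche list 4 of 8 rose, 5 when adjusted over the list alone, including TAA1 by 1.62 ± 0.37, at a median of 1.70 (camera adjusted p = 1.6e-05, and adjusted p = 0.0968 with an estimated correlation). G2 and mitosis had 4 of 9 higher, 6 when adjusted over the list alone, at a median of 1.33 with the same p-values, and S phase had 1 of 5 higher, MCM3 by 1.78 ± 0.37, and 3 when adjusted over the list alone (camera adjusted p = 0.00132, and adjusted p = 0.113 with an estimated correlation). The Casparian list had 3 of 6 lower, 5 when adjusted over the list alone, at -2.09 (camera adjusted p = 2.31e-07, and adjusted p = 0.0968 with an estimated correlation). Stress genes were at a median of -0.69 (camera adjusted p = 0.00966, and adjusted p = 0.0968 with an estimated correlation), with 1 of 11 lower, RBOHD by -2.22 ± 0.48. PLT1 differed by 1.77 ± 0.50 at an adjusted p of 0.0646. Among the largest changes were the expansin-like gene EXLA2 (4.26 ± 0.58) and the iron superoxide dismutase gene FSD1 (3.79 ± 0.57) upwards and the vacuolar dicarboxylate transporter gene TDT (-4.62 ± 0.40) downwards. Organellar medians moved the other way here, by -0.49 for plastid and -0.56 for mitochondrial genes. Without 24 h replicate 2 only 14 genes passed, without 96 h replicate 2 or 3 there were 119 and 174, and without 0 h replicate 5 there were 801. Quantile normalization gave 250 genes, with 41.6% higher, one fit of all 26 arrays 707, the treated arrays alone 795 and a replicate block 978.

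Single steps between treated times called few genes. With limma 0 genes passed from 24 h to 48 h and 0 from 72 h to 96 h, with 399 and 583 at an unadjusted p under 0.05. From 48 h to 72 h 14 genes passed and all fell, among them the lignan reductase gene PRR1 by 3.43 ± 0.44 (n = 2 each, adjusted p = 0.023) and the galactosidase gene BGAL12 by 2.99 ± 0.45. This count was 31 without 0 h replicate 5, and at most 1 without any single array at 24, 48 or 72 h. Array weights gave 58 genes, 6 of them higher, one fit of all 26 arrays 36 with 5 higher, the treated arrays alone 31 with 3 higher, and a replicate block 44 with 5 higher. Plain eBayes gave 0 genes, a pseudocount of 64 gave 3 and one of 1 gave 7. For 72 h to 96 h the fit of all arrays gave 16, the block 14, the treated arrays alone 5 and array weights 2.

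To ask whether the profile of the sorted cells moved towards the QC, genes that separate the QC from the meristem were followed in the time series. No array was shared. Each array measured a pool of sorted cells, so a change within cells cannot be told apart from a changed share of cell types. The QC cells were protoplasted and sorted and the meristems were whole, and genes of stress and protoplasting also stood higher in the QC. The sets therefore do not measure QC identity alone. Of 1681 tested genes enriched in the QC, 609 rose and 295 fell at 24 h, and of 1637 depleted in the QC, 145 rose and 706 fell. The median log2 change of the QC-enriched genes against 0 h was 0.52 at 24 h, 0.52 at 48 h, 0.54 at 72 h and 0.40 at 96 h, beside -0.19, -0.14, -0.07 and -0.05 for all genes outside both sets. With sets of genes differing by at least 2 on the log2 scale, the value at 96 h was 0.06 and did not pass. Camera gave p = 2.88e-06 at 24 h and 0.00456 at 96 h, and p = 0.00641 and 0.0478 with an estimated correlation. The QC-depleted genes stood at -0.79, -0.75, -0.66 and -0.65 (p = 4.74e-07 at 24 h and 2.53e-05 at 96 h, and p = 0.0711 and 0.117 with an estimated correlation). Organellar genes are part of the QC-enriched set: among nuclear genes alone its medians were 0.39, 0.46, 0.45 and 0.30, and with an estimated correlation p = 0.0987 at 96 h. From 24 h to 96 h the QC-enriched set did not gain further, with a median of -0.12 (p = 0.00156, and p = 0.0326 with an estimated correlation), or -0.07 among nuclear genes alone (p = 0.0681 with an estimated correlation).

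Set directly beside the separate QC harvest, untreated SCR cells differed in 5880 genes (2927 higher, 2953 lower, n = 3 each). TEL1 stood at -3.94 ± 0.32 (adjusted p = 1.26e-07), BBM, near background at 0 h, at -3.89 ± 0.32 and PLT1 at -3.08 ± 0.37, while CASP2 was higher by 3.25 ± 0.27 and CASP4 by 3.49 ± 0.38. In the niche list 7 of 9 were lower, at a median of -1.68 (camera adjusted p = 0.00203, and adjusted p = 0.295 with an estimated correlation), and in the Casparian list 4 of 6 were higher, at 2.72 (camera adjusted p = 0.0025, and adjusted p = 0.295 with an estimated correlation), with the same counts when adjusted over each list alone. JKD was lower by -1.15 ± 0.42 (adjusted p = 0.0303), SHR by -1.49 ± 0.38, and SCR higher by 0.99 ± 0.34. For JKD this rests on 0 h replicates 1 and 3 (signals of 11.3 and 41.9), as replicate 5 (101.9) lay within the QC range of 88.1 to 138.1. Organellar medians lay at -1.23 for plastid and -1.80 for mitochondrial genes.

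Treated cells differed from the QC in fewer genes: 3630 at 24 h, 3510 at 48 h, 2870 at 72 h and 3472 at 96 h (n = 2 against 3). Leaving out single arrays took these to as few as 2204 (24 h replicate 2), 1856 (48 h replicate 3), 1327 (72 h replicate 2) and 2279 (96 h replicate 2). At each of 24, 48 and 72 h, 3 of 3 epidermis genes and 6 of 7 root hair markers were lower than in the QC, with the same counts when adjusted over each list alone. For the root hair markers camera gave adjusted p = 0.000413, 7.88e-05 and 5.74e-06, and adjusted p = 0.0907, 0.0899 and 0.0745 with an estimated correlation. At 24 h all 6 S phase genes and 8 of 9 genes of G2 and mitosis were lower, also when adjusted over the lists alone. Their medians were -2.23 and -1.76 (camera adjusted p = 0.000413 for both, and adjusted p = 0.0905 with an estimated correlation). MCM3 stood at -2.78 ± 0.31 and HIK at -2.71 ± 0.38. HIK signal was 15 and 43.3 at 24 h and 204.4 to 305.8 in the separate harvest. It was only 69.06 to 83.81 in the QC arrays grown with jkd, a smaller gap. TAA1 (-3.94 ± 0.31), TEL1 (-4.15 ± 0.35) and PLT1 (-3.37 ± 0.42) were also far below the QC. At 72 h only 1 of 9 genes of G2 and mitosis was lower, PLT1 was at -1.49 ± 0.42 and TAA1 at -2.96 ± 0.31. The Casparian genes, higher than in the QC at 0 h, were lower in 4 of 6 cases (camera adjusted p = 0.00124, and adjusted p = 0.193 with an estimated correlation), CASP5 at -5.41 ± 0.39, with the same count when adjusted over the list alone.

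At 96 h the niche list stood on both sides of the QC, with 3 of 9 higher and 4 lower, 4 and 4 when adjusted over the list alone, a median of 0.67 and a mean of -0.03. MYB56 was higher by 2.31 ± 0.40 and ERF115 by 2.22 ± 0.39, while TAA1 was at -2.32 ± 0.31, TEL1 at -2.06 ± 0.35 and PLT1 at -1.59 ± 0.42 (adjusted p = 0.00844). The size for TAA1 depends on the QC harvest at every treated time. Its signal was 195.1 and 308.2 at 96 h, against 1093.6 to 1545.7 in the separate harvest. In the QC arrays grown with jkd it was only 289.74, 442.05 and 318.36. Casparian genes were lower in 5 of 6 cases, at -2.98 (camera adjusted p = 0.000137, and adjusted p = 0.14 with an estimated correlation). Root hair markers were lower in 6 of 7 cases, EXPA18 at -4.64 ± 0.46 and RSL4 at -3.67 ± 0.40 (camera adjusted p = 3.78e-05, and adjusted p = 0.12 with an estimated correlation). The level of these markers in the QC depends on the harvest. With the QC arrays grown with jkd, EXPA18 (-0.74) and RHD6 (0.73) reversed against the meristem. EXPA7 (0.022) reversed at 0 h against the QC, while no named root hair marker reversed at the treated times. All 3 epidermis genes were lower, WER at -5.10 ± 0.75, as were 3 of 5 xylem genes, XCP1 at -4.21 ± 0.46 (camera adjusted p = 0.0295, and adjusted p = 0.12 with an estimated correlation). Cell cycle inhibitors were lower in 4 of 7 cases, CCS52A1 at -2.85 ± 0.39 (camera adjusted p = 0.00174, and adjusted p = 0.12 with an estimated correlation). S phase genes were lower in 3 of 6 cases (camera adjusted p = 0.0307, and adjusted p = 0.256 with an estimated correlation). For the lists from the Casparian genes on, the counts were the same when adjusted over the list alone. SCR was higher than in the QC by 1.75 ± 0.38, as were NAC6 (6.69 ± 0.45) and HB53 (6.11 ± 0.34). The 2 wild type QC harvests differed from each other in 2649 genes, or in 1399 without replicate 2 of the separate harvest. That count comes from another fit with 3 arrays per group, so it is not on one scale with the counts at the treated times.

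**Figure D3:**
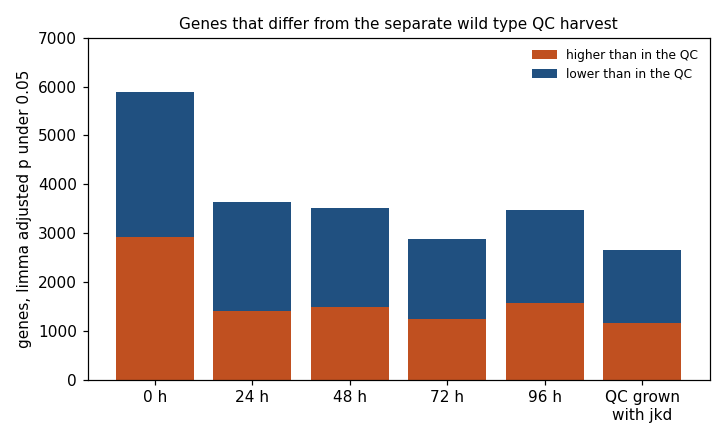
Number of genes (y axis) with a limma adjusted p under 0.05 against the separate wild type QC harvest, stacked as higher (orange) and lower (blue), for SCR cells at 0, 24, 48, 72 and 96 h and, from its own fit of 6 arrays, for wild type QC cells grown with jkd. The count drops from 5880 at 0 h to 2870 at 72 h and is 3472 at 96 h, beside 2649 between the QC harvests. The treated times have 2 arrays each and the other groups 3, and the fits differ, so the counts do not measure distance on one scale. Group means correlated with the separate harvest at 0.808 at 0 h, 0.888 at 72 h, 0.877 at 96 h and 0.931 for the QC grown with jkd.

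In wild type, QC cells differed from the whole meristem in 6690 genes (3098 higher, 3592 lower, n = 3 each), 3565 of them by at least 1 on the log2 scale, and in 4378 in one fit of all 26 arrays. BBM was higher by 3.45 ± 0.21 (adjusted p = 1.17e-08), PLT1 by 3.02 ± 0.24, TAA1 by 2.47 ± 0.17 and the auxin response gene IAA30 by 4.12 ± 0.24, while CYCB1;3 stood at -2.39 ± 0.22. Of the niche list 9 of 10 were higher and 1 lower, at 2.56 (camera adjusted p = 0.000124, and adjusted p = 0.414 with an estimated correlation). Auxin response had 8 of 12 higher, IAA19 by 4.07 ± 0.18 (camera adjusted p = 0.00105, and adjusted p = 0.414 with an estimated correlation), and the Casparian list 5 of 6, CASP2 by 4.24 ± 0.27 (camera adjusted p = 0.00133, and adjusted p = 0.414 with an estimated correlation). CASP2 signals in the wild type meristem were near background (2.11, 21.47 and 15.18), so the size of its difference depends on the pseudocount. All 6 S phase genes and 6 of 9 genes of G2 and mitosis were lower, at -0.94 and -1.20 (camera adjusted p = 0.0203 for both, and adjusted p = 0.414 with an estimated correlation). Auxin synthesis and transport had 6 of 8 higher, YUC7 by 1.85 ± 0.25, and 2 lower, PIN2 at -1.51 ± 0.16. Counts were the same when adjusted over each list alone.

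The QC cells had been protoplasted and sorted, and markers of stress and of organelles stood higher in them as well. Of the stress and protoplasting list 10 of 11 were higher, also when adjusted over the list alone, at a median of 1.45 (camera adjusted p = 5.15e-05, and adjusted p = 0.147 with an estimated correlation), with the NADPH oxidase gene RBOHD up by 4.33 ± 0.23 and HSP70 by 4.11 ± 0.22. Organellar genes were higher in 70 of 78 plastid and 47 of 53 mitochondrial probe sets, at medians of 1.92 and 2.21. JKD was lower in the QC than in the meristem by -0.67 ± 0.21 (adjusted p = 0.0125), and SCR differed by -0.04 ± 0.22 (adjusted p = 0.892). With the QC arrays grown with jkd in place of the separate harvest, SGN3 changed from 2.49 to -0.13. The differences of TAA1 and BBM from the meristem were also smaller there. TAA1 signals were 289.74 to 442.05 in these arrays and 214.04 to 223.38 in the wild type meristem. For BBM they were 154.06 to 192 and 25.87 to 40.5.

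The 2 wild type QC harvests, nominally the same cells, differed in 2649 genes (1161 higher and 1488 lower in the arrays grown with jkd, n = 3 each). HSP17.6A was higher by 3.74 ± 0.25 (adjusted p = 1.41e-06) and HSP101 by 2.14 ± 0.22, and TAA1 stood at -1.86 ± 0.24, BBM at -1.53 ± 0.25 and SGN3 at -2.62 ± 0.37. Of the stress list 6 of 11 were higher and 1 lower, 6 and 2 when adjusted over the list alone, at 0.75 (camera adjusted p = 0.000812, and adjusted p = 0.189 with an estimated correlation). Casparian genes were lower in 4 of 6 cases, 5 when adjusted over the list alone, at -1.28 (camera adjusted p = 0.00454, and adjusted p = 0.371 with an estimated correlation). Auxin synthesis and transport was lower in 2 of 8 cases, 4 when adjusted over the list alone (camera adjusted p = 0.0221, and adjusted p = 0.371 with an estimated correlation). In the niche list 4 of 10 were lower and 1 higher. Plastid genes were higher in 30 of 78 cases and mitochondrial genes in 23 of 58.

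JKD signal followed the genotype in every array of the second experiment. In wild type QC cells it was 68.67, 73.98 and 108.67, and in jkd QC cells 1.37, 24.86 and 6.6. In wild type meristems it was 201.24, 172.76 and 184.47, and in jkd meristems 11.28, 13.35 and 6.23. Whether the probe set lies inside the disrupted part of the gene is not known. The separate QC harvest had 111.3, 88.1 and 138.1.

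In QC cells of jkd, 12 genes passed against the wild type arrays grown with them, 10 higher and 2 lower (n = 3 each). Among those higher were AT3G17100 (4.26 ± 0.49, adjusted p = 0.00156) and AT3G17110 (4.11 ± 0.44, adjusted p = 0.00109), which lie next to each other on chromosome 3 and whose wild type signals near background leave the size of the difference to the pseudocount. IDD7, a zinc finger gene of the same family as JKD, was higher by 2.53 ± 0.46 (adjusted p = 0.0492), TI1, a trypsin inhibitor gene, by 2.28 ± 0.34, and AT1G33055 by 2.93 ± 0.47. Lower were the root hair gene PRP3 at -2.18 ± 0.39 (adjusted p = 0.0492) and the copper chaperone gene CCH at -1.88 ± 0.33. JKD itself stood at -1.96 ± 0.52 without passing (adjusted p = 0.204), and so did SCR at -1.47 ± 0.46 (adjusted p = 0.3), SHR at -1.14 ± 0.53 (adjusted p = 0.549) and PLT1 at -0.77 ± 0.43 (adjusted p = 0.63). At an unadjusted p under 0.05 there were 1036 genes. One fit of all 26 arrays called 436 genes, only 112 of them higher, array weights 53 with 24 higher, and a replicate block 41 with 25 higher. Plain eBayes called only 2 genes and a pseudocount of 1 called 7.

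As lists in jkd QC cells, root hair markers had 1 of 7 lower, 4 when adjusted over the list alone, at a median of -1.28 (camera adjusted p = 0.000357, and adjusted p = 0.157 with an estimated correlation). Of the Casparian genes 0 of 6 passed with limma, 3 lower when adjusted over the list alone, at -1.16 (camera adjusted p = 0.00131, and adjusted p = 0.157 with an estimated correlation), and CASP5 was at -3.40 ± 0.62 (adjusted p = 0.0522). Stress genes had a median of 0.23 (camera adjusted p = 0.0369, and adjusted p = 0.31 with an estimated correlation), with 0 of 11 passed. Over the list alone, 2 of 8 genes of the SHORT-ROOT and SCARECROW network, 3 of 6 xylem and 2 of 2 phloem genes were lower, against 0 over all genes. Of the niche list 0 of 10 passed by either adjustment. Organellar medians differed by 0.04 for plastid and -0.08 for mitochondrial genes. Leaving out single arrays gave 2 to 10 genes, with 2 without jkd QC replicate 3 and 6 without replicate 3 of the wild type arrays.

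In the meristem 107 genes passed, 89 higher and 18 lower in jkd (n = 3 each). JKD was lower (-2.95 ± 0.19, adjusted p = 2.31e-06), and single genes of flavonoid synthesis and of the cold and drought response were higher. The chalcone synthase gene TT4 was higher by 2.53 ± 0.20 (adjusted p = 1.42e-05), the flavonol synthase gene FLS1 by 2.41 ± 0.19, F3H by 2.23 ± 0.17 and LTI78, a cold and drought gene, by 2.87 ± 0.27. AT3G17090 (5.40 ± 0.19, adjusted p = 2.32e-09) and its neighbour AT3G17100 (5.38 ± 0.24) were also higher, from wild type signals near background that leave the size of the difference to the pseudocount. Lower were CASP5 at -1.71 ± 0.24 (adjusted p = 0.00252), the iron uptake regulator gene bHLH39 at -1.49 ± 0.25 and the cell wall gene XTH16 at -1.21 ± 0.20. SCR (-0.42 ± 0.18, adjusted p = 0.546), SHR (0.09 ± 0.25, adjusted p = 0.998) and PLT1 (-0.17 ± 0.28, adjusted p = 0.998) did not pass.

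Among the lists in the jkd meristem, stress genes had 1 of 10 higher, HSP17.6A by 1.47 ± 0.23, and 2 when adjusted over the list alone, at a median of 0.26. Auxin synthesis and transport stood at 0.25 and cell cycle inhibitors at -0.22, each with 0 of 7 passed by limma over all genes, and 1 and 0 when adjusted over the list alone. For these 3 lists camera gave an adjusted p of 0.0199, and an adjusted p = 0.388 with an estimated correlation. Casparian genes had 1 of 4 lower, CASP5, and 2 when adjusted over the list alone. The network list had 1 of 9 lower, JKD itself, also when adjusted over the list alone, with a median of 0.00 and a mean of -0.30. The niche list had 0 of 8 passed by either adjustment. Organellar medians differed by -0.04 and 0.17. Leaving out single arrays gave 50 to 82 genes, with 50 and 63 without jkd meristem replicates 1 and 2 and 65 without wild type meristem replicate 3. One fit of all 26 arrays called 16, a filter at the 50th percentile 53, no filter 60, a replicate block 187 and array weights 190.

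**Figure D4:**
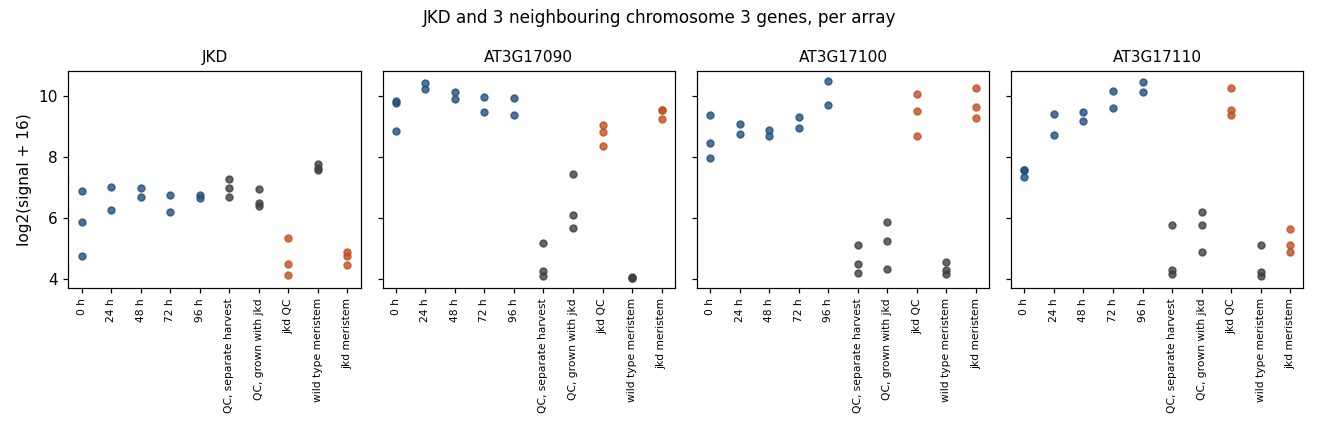
Log2(signal + 16) per array of JKD and of AT3G17090, AT3G17100 and AT3G17110 in all 10 groups (blue, SCR sorted cells by hours of 2,4-D, dark grey, wild type QC and meristem, orange, jkd). Wild type meristem arrays have AT3G17090 signals of 0.47 to 0.62, against 595.72 to 726.7 in jkd meristems and 446.5 to 1359.7 in SCR sorted cells.

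Between the tissues, 10503 genes were tested for jkd in both. Of these 8 passed in the QC and 91 in the meristem, with 3 in common where independent lists would share 0.0693 (Fisher's exact test, two-sided p = 3.42e-05), all 3 in the same direction. The 3 were NAP, AT3G57020 and AT3G17100, and for AT3G17100 a variant of a plant line may explain the difference. Fisher's test also treats genes as independent of each other. Of the 79 genes higher in the jkd meristem, 63 were also higher in the jkd QC, at a median of 0.60, and of 12 lower, 11 were lower there, at -0.84, beside -0.10 for all genes. The test of the difference itself called 0 genes with limma, with 909 at an unadjusted p under 0.05, and at most 30 under the other settings, with array weights. For the lists it gave -0.83 for auxin synthesis and transport (camera adjusted p = 0.00453, and adjusted p = 0.227 with an estimated correlation) and -1.06 for root hair markers (camera adjusted p = 0.00453, and adjusted p = 0.322 with an estimated correlation). Of their genes 1 and 2 passed when adjusted over the list alone, against 0 and 0 over all genes.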

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

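The tests of this part, of the difference of the jkd effect between QC and meristem, were fixed before the data were seen, and the 3 single genes were picked by their result. For the auxin synthesis and transport genes that difference had a median log2 value of -0.83 (adjusted p = 0.00453, and adjusted p = 0.227 with an estimated correlation), from medians of -0.65 in the QC and 0.25 in the meristem. For the root hair markers it was -1.06 (adjusted p = 0.00453, and adjusted p = 0.322 with an estimated correlation), from -1.28 in the QC and -0.18 in the meristem.

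Of 96 genes tested in both tissues and called for jkd in either, 3 had arrays that separated completely in opposite directions in the 2 tissues. A call in a tissue nearly implies separation there, and chance separates 3 arrays from 3 in 10% of cases in either direction, so 3 of 96 is no excess. For CRY3, a cryptochrome gene, the difference was -2.11 (adjusted p = 0.118), from -0.86 in the QC and 1.25 in the meristem. For HVA22D, a gene induced by abscisic acid, it was -2.24 (adjusted p = 0.12), from -0.71 in the QC and 1.54 in the meristem. For AT3G22240 it was 2.07 (adjusted p = 0.0781), from 1.03 in the QC and -1.04 in the meristem.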

How the results depend on the processing

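The alternatives were fixed before the data were seen, except the comparison of 96 h with 24 h, the tests on treated arrays only and without the 0 h arrays, those without organellar probe sets, and the block for the QC against the meristem and for the QC harvests. Of 16420 values for 762 results on named genes, 15507 kept their call, 863 became weaker, 28 stronger and 22 reversed. Of 4702 values for 214 list results, 4498 kept it, 140 became weaker, 64 stronger and 0 reversed. The other deposited table of the same arrays gave identical values.

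All 22 reversals came with the QC arrays grown with jkd used as the QC. They were IAA28 (0.56), TAA1 (0.29), HIK (0.21), CCS52A1 (0.33), EXPA7 (0.022) and JAZ10 (-0.43) for 0 h against the QC. At 24 h they were CASP2 (0.44), GH3.6 (0.028), GA2OX8 (0.41) and GA2OX6 (1.14), and at 48 h GA2OX8 (0.037). At 72 h they were MCM3 (0.012), GA2OX6 (0.68) and BRN1 (0.13), and at 96 h GH3.6 (0.74), MCM3 (0.17), GA2OX6 (0.24) and RBOHD (0.34). For the QC against the meristem they were SGN3 (-0.13), IAA28 (-0.13), RHD6 (0.73) and EXPA18 (-0.74).

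Array weights gave 1 gene from 24 h to 48 h (0 without them), 58 from 48 h to 72 h (14), 2 from 72 h to 96 h (0), 53 and 190 for jkd in QC and meristem (12 and 107) and 30 for their difference (0). One fit of all 26 arrays gave 1, 36 and 16 for the single steps, 707 from 24 h to 96 h (443), 4378 for the QC against the meristem (6690), 436 and 16 for jkd in QC and meristem and 9 for their difference. Treated arrays only gave 1, 31 and 5 for the steps and 795 from 24 h to 96 h. A pseudocount of 1 gave 7 from 48 h to 72 h, 7 for jkd in the QC and 2 for the difference, and one of 64 gave 1 from 24 h to 48 h, 3 from 48 h to 72 h and 7 for the difference. Plain eBayes gave 0 from 48 h to 72 h and 2 for jkd in the QC. For jkd in the meristem no filter gave 60 and a filter at the 50th percentile 53. Quantile normalization gave 250 from 24 h to 96 h, and 41.6% of these were higher at 96 h, against 226 of 443. A change of at least 1 on the log2 scale left 3565 for the QC against the meristem. Without the 0 h arrays the series had 1026 genes with a trend per day and 501 by a moderated F test, against 5926 with them.

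With an estimated correlation 0 of 69 list shifts remained. The QC-depleted shifts of -0.79, -0.75, -0.66 and -0.65 at 24, 48, 72 and 96 h then had p-values of 0.0711, 0.069, 0.0976 and 0.117. With sets of genes differing by at least 2 on the log2 scale, the QC-enriched shift at 96 h was 0.06 and did not pass with camera. Without organellar probe sets 24 h against 0 h gave 5550 genes and the enriched shifts were 0.39, 0.45, 0.44 and 0.29.

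With the replicate number as a block, the treated arrays gave 1, 44 and 14 for the single steps and 978 from 24 h to 96 h, and jkd gave 41 in the QC and 187 in the meristem. The labels give these numbers without saying that samples were paired. The mean of its group was taken from each array, and these deviations were correlated between arrays of the same number. The values were -0.04 to 0.05 for jkd in the QC, -0.11 to -0.04 in the meristem and -0.03 to 0.18 between treated times. The jkd and wild type samples may therefore share only a number. Between treated times the value was positive for every pair of times except 72 h and 96 h (-0.03), and highest for 24 h and 48 h (0.18). Pairing of the treated arrays by number therefore stays open.

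As single arrays were left out, the lowest and highest counts against 0 h were 3871 and 5670 at 24 h, 3754 and 5815 at 48 h, 3757 (without 72 h replicate 2) and 5797 at 72 h, and 4502 and 6152 at 96 h, with 4865 and 6084 for the joint test. Where 1 of 2 arrays was left out, the other was taken to vary as the remaining groups do. For the single steps they were 0 and 1 (without 0 h replicate 5 or 48 h replicate 3), 0 (without any array at 24, 48 or 72 h except 72 h replicate 2, which gave 1) and 31 (without 0 h replicate 5), and 0 and 6 (without 96 h replicate 3, beside 5 without 0 h replicate 5 and 1 without either 48 h array). From 24 h to 96 h they were 14 (without 24 h replicate 2) and 801 (without 0 h replicate 5), with 119 and 174 without 96 h replicates 2 and 3.

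Against the QC they were 4977 and 6177 at 0 h, 2204 (without 24 h replicate 2) and 4417, 1856 (without 48 h replicate 3, and 2014 without replicate 2) and 4283, 1327 (without 72 h replicate 2) and 3691, and 2279 (without 96 h replicate 2) and 4236. They were 5933 and 6364 for the QC against the meristem. The QC harvests gave 1399 (without separate QC replicate 2, with 1454 and 1548 without replicates 1 and 3) and 3407. For jkd they were 2 (without jkd QC replicate 3, and 6 without wild type replicate 3) and 10 in the QC, 50 (without jkd meristem replicate 1, with 63 without replicate 2 and 65 without wild type replicate 3) and 82 in the meristem, and 0 and 5 (without jkd QC replicate 2, with 3 and 2 without replicates 1 and 3) for the difference. Enriched shifts ranged over 0.43 to 0.54, 0.45 to 0.63, 0.47 to 0.58 and 0.34 to 0.44, and depleted shifts over -0.90 to -0.68, -0.79 to -0.68, -0.70 to -0.55 and -0.67 to -0.55. The cause was not tested for any of these differences.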

Other observations

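From 24 h to 96 h, among the 8 treated arrays alone, a linear trend per day was added after the data had been seen, and 1026 of 11469 genes passed, 570 rising and 456 falling. MYB56 rose by 1.12 ± 0.14 per day on the log2 scale (adjusted p = 0.000401), BBM by 0.71 ± 0.12 (adjusted p = 0.00234), TEL1 by 0.72 ± 0.13 and PLT1 by 0.63 ± 0.15 (adjusted p = 0.0157). MYB36, the transcription factor that switches on the Casparian strip genes, fell by 1.01 ± 0.11 per day (adjusted p = 0.000186), and SGN3 fell by 0.98 ± 0.10. Of the tested genes 6 of 9 in the niche list rose, with 3 of 5 in S phase, 5 of 9 in G2 and mitosis and 3 of 6 in auxin synthesis and transport, while all 5 of the Casparian list fell. SCR (0.15, adjusted p = 0.48) and JKD (-0.02, adjusted p = 0.95) did not pass.

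The tests of this paragraph and the next 2 on organellar signal, nuclear calls and chromosome 3 genes were chosen after seeing the result, and those on splits before it. The clock, flavonoid and cold gene sets were chosen after the jkd meristem calls had been seen, before the values of the sets themselves. Organellar transcripts stood higher in treated cells than at 0 h, by 1.19 for plastid and 1.32 for mitochondrial genes. A difference in handling may explain this, since 0 h replicate 5 alone stood 2.64 above replicates 1 and 3 for plastid genes and 1.89 for mitochondrial genes. An effect of 2,4-D stays open, as 1 of 8 treated arrays lay above every 0 h array for plastid genes and 4 of 8 for mitochondrial genes. Across nuclear genes, the difference of replicate 5 from the others correlated at -0.082 with the change at 24 h, but both hold the 0 h arrays, so the value cannot tell whether handling adds calls. A difference between harvests alone could also call many genes, as 2649 were called between the QC harvests, against 5522 at 24 h.

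The neighbouring genes AT3G17090 and AT3G17100 of chromosome 3 stood higher in every jkd QC array than in the separate wild type QC harvest, with a gap of at least 3.17 on the log2 scale. Among the wild type QC arrays grown with jkd AT3G17090 reached 158.82, against 312.26 in the lowest jkd array, and did not pass (2.34, adjusted p = 0.0763). In 7 arrays of cells sorted with the SCR promoter, JKD signal was at or above 68.67 and both genes were above every wild type QC array. The same held in all 11 such arrays, whatever their JKD signal. These cells carried another reporter and may come from another plant line, so the values cannot tell whether JKD lowers these genes. A variant of the wild type line or of the jkd line at these genes may explain the pattern, and an effect of JKD stays open. The adjoining AT3G17110 passed in the QC (4.11), but its signal was 13.46 to 34.15 in jkd meristems and 1.35 to 19.03 in wild type ones, and of 13 neighbours beyond these 3 genes 8 were tested and 0 called in either tissue with limma.

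In the jkd meristem TT4, FLS1 and F3H of flavonoid synthesis and LTI78 of the cold response were higher. The sets of this paragraph left out the genes already called in the jkd meristem, so none of their members could pass singly there. The 5 tested evening clock genes had a median of 0.50 (camera p = 1.3e-06, and p = 0.0266 with an estimated correlation). The 6 morning clock genes had a median of -0.14, with 2 higher (camera p = 0.443, and p = 0.649 with an estimated correlation). Called genes left out include the morning clock gene LHY (-0.97, limma adjusted p = 0.0246) and COR27 (1.39, limma adjusted p = 0.00468). The evening genes lay 0.64 above the morning genes, so the meristems may have been cut at different times of day. Other cold and drought genes were higher by a median of 0.58 (8 of 9, camera p = 0.00897 with an estimated correlation), so a cold or drought response as a whole could also explain the higher genes. A rise of flavonoid synthesis as a whole cannot be told from 2 tested genes at 0.26. In the jkd QC the cold and drought genes stood at 0.15 (p = 0.373 with an estimated correlation).

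Splitting 6 arrays into 3 and 3 allows 10 splits, too few for a share under 0.05. The real split gave 12 genes for jkd in the QC, 107 for jkd in the meristem, 6690 for the QC against the meristem, 2649 for the QC harvests and 5880 for 0 h against the QC. In each of these 5 cases the highest other split gave 0, so that 1 of 10 reached the real count. For the difference of the jkd effect between tissues, the real count was 0, so all 100 drawn splits reach it and nothing follows about chance. The highest, 78, came from the split that kept the QC groups and exchanged wild type and jkd in the meristem. That split tests the sum of the jkd effects in QC and meristem. A gene changed in the meristem alone can also pass it, so the 78 calls do not measure a shared effect. The highest of the other splits gave 7.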
